A study of Homo sapiens with 9 samples.

How the data were processed

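RNA from MDA-MB-231 cells was measured on Illumina bead arrays 72 h after transfection, with 3 arrays for each of 3 groups (Luc, KD1 and KD2) and thus 9 arrays in all. Biotin-labelled cRNA was made with the Ambion MessageAmp kit, per the labels. The scanner and the software that exported the table are not given in the sources used here. The deposited signal intensities are bead-summarised probe values on a linear scale, neither background-subtracted nor normalized between arrays, per the file headers and the values. The detection p-value of each probe on each array was deposited beside its intensity, per the file headers, and falls as the signal rises. The deposited series values are on a scale near log2 and are quantile-normalized between arrays, as the values show, and lumi is the tool in the submitters' processing notes, with its version and steps not given in the sources used here. The median of the deposited log2 values was 7.602 on every array, and the rank order on each array equalled that of the intensities.

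The intensities were processed in limma 3.58.1 under R 4.3.3. The neqc function corrected the background by a normal-exponential model whose negative-control level was inferred from the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. Symbols came from the annotation of the deposited table's probes and were updated through Entrez identifiers with a RefSeq gene table of assembly GRCh38.p14, used only for names: of 48799 probes, 28094 had 1 symbol (28055 updated, 39 kept as given), 13 had several and 20692 had none. For each of 18850 symbols the probe with the highest mean over all arrays was used, and probes without a single symbol stayed as features of their own, which gave 39555 features. The 13076 features with a detection p under 0.05 on at least 3 arrays were tested, 10264 with a symbol and 2812 without. Detection ranged from 29.8% to 35.9% of probes per array, and the median residual SD over tested features was 0.217 on the log2 scale.

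No probe carried the symbol KDM5A, so its level was left out. A probe with the file symbol RBP2 belongs to retinol-binding protein 2 and was not taken for the target, which shares that older name. No per-sample column was left unused.

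A linear model with a mean per group was fitted to all 9 arrays with lmFit and eBayes, with 6 residual and 10.2 total degrees of freedom. Tests were two-sided, and a call is a Benjamini-Hochberg adjusted p under 0.05 over all tested features. The comparisons were KD1 against Luc, KD2 against Luc, the mean of both against Luc, and KD1 against KD2, and a feature counted for both siRNAs when each gave a call of the same sign. An exact permutation test of 3 against 3 arrays cannot go below a two-sided p of 0.1, so none was used for single genes. Where a group had no array with detection, the fold is a lower bound against the detection floor on the scale of the main processing only, since folds of dim probes shrink with a larger offset or no background correction.

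Gene lists were written from general knowledge before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. The 31 lists were the KDM5 family, other histone demethylases, H3K4 methyltransferase complexes, lung metastasis, bone metastasis, matrix proteins, integrins and adhesion, matrix proteases, mesenchymal, epithelial, luminal breast, leukocyte, fibroblast, S phase and DNA replication, mitosis, CDK inhibitors, p53 targets, interferon-stimulated genes, NF-kB and cytokines, TGF-beta targets, YAP targets, receptor tyrosine kinases and ligands, hypoxia and glycolysis, oxidative phosphorylation, mitochondrial ribosome, cytosolic ribosome, cholesterol synthesis, unfolded protein response, HOX genes, histone genes and siRNA machinery. They hold 915 genes, of which 852 were on the array and 687 were measured. Lists with at least 3 measured members, 30 in all, were tested with camera from limma at a preset gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry.

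Named for both siRNAs were the 12 higher and 12 lower genes with the largest smaller absolute log2 fold change, among those where no KD1 or KD2 array overlapped the Luc arrays. Chance can also give such a separation with so few arrays. For each siRNA and for KD1 against KD2, the 5 higher and 5 lower genes with the largest absolute log2 fold change were named, with up to 4 called genes of each list. KDM5A, KDM5B, KDM5C, TNC, MMP1, VIM, CDH1, CDKN1A, CDKN1B, IFIT1 and ISG15 were always named where measured, and features without a single symbol or with a predicted symbol were passed over.

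The procedure was tested on simulated data for the 13076 tested features with known changes. For KD1 against Luc it recovered 8.96% of 67 genes changed by 0.5 on the log2 scale, 68.7% of 67 changed by 1 and 98.5% of 66 changed by 2, with 8 false calls among 12876 unchanged genes. For KD2 against Luc the shares were 8.96%, 67.2% and 97.0%, with 7 false calls, and for both siRNAs against Luc they were 5.97%, 61.2% and 95.5%, with 2 false calls. Changes near 0.5 were therefore mostly missed in this simulation, where few features changed. In the data 2157 features were called with KD1 and 2927 with KD2, which eases the adjusted threshold. The shares therefore do not give the sensitivity of the real comparisons.

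Alternatives were no background correction, median scaling in place of quantile normalization, an offset of 50, the deposited log2 values, no detection filter, a detection p under 0.01 on all 9 arrays, every probe as a feature, an intensity trend with robust variances, only the 2 groups compared, a block for the replicate number, array weights, an absolute log2 fold change of at least 1, and each array left out in turn. Median scaling moved the median log2 fold change of all features to 0.0893 with KD1 and 0.0595 with KD2. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.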

Results

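Transcript levels were measured in MDA-MB-231 cells, an established human breast cancer line with mesenchymal features, 72 h after transfection of a small interfering RNA. The cells received siRNA 1 against KDM5A (KD1), siRNA 2 against KDM5A (KD2) or an siRNA against luciferase as the control (Luc), with 3 arrays in each group. KDM5A, also called RBP2 or JARID1A, removes methyl groups from lysine 4 of histone H3. The comparisons ask which transcripts change when KDM5A is targeted, and which of these changes are shared by both siRNAs. Of 48799 probes, between 14529 (KD1 replicate 3) and 17538 (Luc replicate 3) were detected on an array. Pearson correlations between arrays over the tested features were 0.986 to 0.989 within groups and 0.963 to 0.9749 between groups. No array held the same values as another. The Luc and KD2 arrays lay at positions A to F of the slide and the KD1 arrays at G, I and K. An effect of those positions therefore cannot be told apart from an effect of KD1. The number of arrays limits the precision, and since the labels do not say that the arrays came from separate cultures, p-values measure only the spread between these samples, which may be technical.

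The level of KDM5A itself is not analysed here, because none of the probe annotations used here carried that symbol. The extent of the knockdown is therefore not given, and KD1 and KD2 are described as the labels name them. Of the other members of the KDM5 family on the lists, KDM5C was not detected on enough arrays to be tested. KDM5B, a close relative of KDM5A, had a mean log2 intensity of 9.95 ± 0.08 in Luc, 10.41 ± 0.09 in KD1 and 10.22 ± 0.02 in KD2 (SD, n = 3 arrays each). It was higher with KD1 (log2 fold change 0.45, SE 0.12, adjusted p = 0.0237) and was not called with KD2 (0.27, adjusted p = 0.122). The siRNAs did not differ by the test for KDM5B (adjusted p = 0.271). The KDM5B call was lost without Luc replicate 1 (adjusted p = 0.0754), Luc replicate 2 (0.0520), Luc replicate 3 (0.0529), KD1 replicate 1 (0.0793) or KD1 replicate 2 (0.0507), and over all 9 arrays left out in turn the adjusted p ran from 0.0343 to 0.0793.

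HMOX1, the inducible heme oxygenase that degrades heme, had the largest rise shared by both siRNAs. Its mean log2 intensity was 6.62 ± 0.15 in Luc, 9.28 ± 0.06 in KD1 and 10.26 ± 0.11 in KD2 (SD, n = 3 each). It was 6.31-fold higher with KD1 and 12.4-fold higher with KD2. Several histone transcripts rose as well. H2AC18 rose by 2.07 with KD1 and 2.06 with KD2 on the log2 scale, H1-2 by 1.83 and 1.86, H2AC20 by 1.64 and 1.93, and H2BC21, detected on 1 of 3 Luc arrays, by 1.79 and 1.65. The deubiquitinase gene OTUB2 rose by 1.81 and 2.32, the splicing factor gene SF3B5 by 1.49 and 1.73, APCDD1L by 1.43 and 1.70, and MLX, which encodes a transcription factor partner of the MondoA and ChREBP proteins, by 1.41 and 1.67. RBPMS2 was 3.02-fold higher with KD1 and 2.46-fold higher with KD2. CDC42SE2 rose by 1.58 and 1.31, although a second, dimmer CDC42SE2 probe was not called (0.34 and 0.00). ALDH4A1, a mitochondrial enzyme gene of proline breakdown, was not detected on any Luc array and was at least 2.17-fold higher with KD1 and at least 2.56-fold higher with KD2 on the background-corrected scale used here. On the deposited normalized values the differences for ALDH4A1, KD1 against Luc, and ALDH4A1, KD2 against Luc, were 0.31 and 0.37 in log2, both called. A second ALDH4A1 probe was called higher with both (1.17 and 1.16) and another was not called.

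Among the genes lower with both siRNAs, PNO1, which encodes a ribosome assembly factor, was 4.27-fold lower with KD1 and 3.04-fold lower with KD2. Its mean log2 intensity in Luc was 8.90 ± 0.05 (SD, n = 3). Log2 fold changes with KD1 and KD2 were -1.53 and -1.52 for XAF1, an interferon-inducible gene, -1.51 and -1.48 for IL11, a cytokine, and -1.67 and -1.45 for MAPK8, which encodes the kinase JNK1. ITGB2, the gene of the beta chain of leukocyte integrins, changed by -1.39 and -2.40, with a second probe at -1.22 and -1.88. Also lower were TMX1, which encodes a thioredoxin-like membrane protein (-2.75 and -1.24), CLGN, a chaperone gene (-1.34 and -1.42), and MAN1A2, a mannosidase gene (-1.40 and -1.39, with a second probe not called). The remaining genes were MSRB3 (-2.22 and -1.35, with 1 of its other probes not called), SNCAIP (-1.85 and -1.21), SCARF2 (-1.60 and -1.27) and GPR180 (-1.27 and -1.69, with a second, dimmer probe not called at -0.31 and 0.20). The adjusted p-values of these 24 genes from limma were at most 0.0122, and 0 of the 24 lost a call when any of the 9 arrays was left out. Both are favoured by the choice of these genes on the same arrays for large changes without overlap, so neither is separate support. The sizes depend on the scale: over the 238 called values of named genes, log2 fold changes on the deposited normalized values were 65.6% of those given here in the median (21.1% to 102%).

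**Figure D1:**
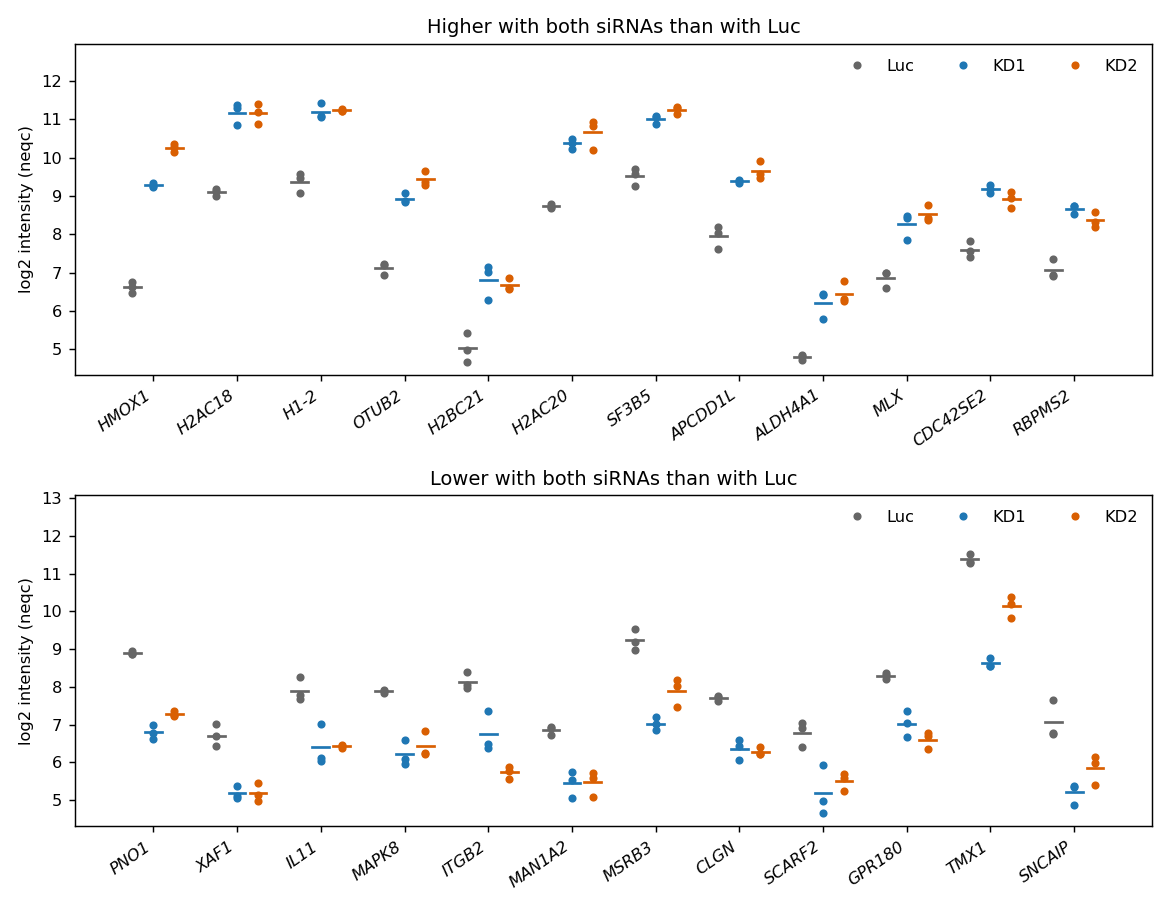
Normalized log2 intensity of the 24 genes named for both siRNAs, with 1 point per array, a bar at each group mean, and 3 arrays each for Luc (grey), KD1 (blue) and KD2 (orange). HMOX1 rises from a mean of 6.62 in Luc to 9.28 in KD1 and 10.26 in KD2, and PNO1 falls from 8.90 to 6.80 and 7.29.

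In all, 708 of 13076 tested features were called with the same sign by both siRNAs, 362 higher and 346 lower, at an adjusted p under 0.05 in each. Of these, 89 had an absolute log2 fold change of at least 1 with each siRNA (50 higher, 39 lower). Lists of that length drawn independently would share 102.8 higher and 139.4 lower features. A further 163 features were called in opposite directions, against 240.6 for independent lists. Both comparisons use the same 3 Luc arrays, so unchanged groups and their shared controls were simulated in 100 runs. The runs gave a correlation of log2 fold changes of 0.50 (observed 0.309) and the same sign in 66.6% of features (observed 61.6%). Their covariance was 0.0232 (observed 0.0678, a difference of 0.0446). They called 0 features with the same sign in both comparisons (observed 708). The measured Luc arrays were not part of the runs, so a shift particular to those arrays was not tested. The 3 control arrays cannot be split into parts of at least 2, so part of the excess may come from the shared controls. The count for both siRNAs against Luc was 465 without Luc replicate 1 and 410 without Luc replicate 2, 1107 without background correction, 1113 on the deposited normalized values and 461 without the detection filter. With median scaling in place of quantile normalization, both siRNAs against Luc gave 465 higher and 293 lower, in place of 362 higher and 346 lower.

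For the mean of both siRNAs against Luc, 2259 features were called, 1023 higher and 1236 lower. Leaving out Luc replicate 1 or Luc replicate 2 gave 1363 and 1204 calls, and an absolute log2 fold change of at least 1 left 241. With median scaling the split of this comparison (both siRNAs against Luc, mean contrast) was 1383 higher and 1089 lower, in place of 1023 higher and 1236 lower. In this mean contrast the lists called by camera were lower for matrix proteins (adjusted p = 1.62e-04), YAP targets (2.44e-04), the unfolded protein response (4.36e-04), interferon-stimulated genes (0.00977) and integrins and adhesion (0.0439), and higher for oxidative phosphorylation (1.62e-04), histone genes (8.26e-04) and cholesterol synthesis (0.00591). None was called with an estimated correlation, where the lowest adjusted p = 0.125 with an estimated correlation belonged to interferon-stimulated genes, cholesterol synthesis and the unfolded protein response. Of the 30 lists tested by camera, 7 had an unadjusted p under 0.05 there. With KD2 alone, camera at the preset correlation did not call matrix proteins (adjusted p = 0.957), integrins and adhesion (0.957), interferon-stimulated genes (0.358) or cholesterol synthesis (0.187). With KD1 alone it did not call the unfolded protein response (adjusted p = 0.554). A call in the mean contrast therefore does not show that a list moved with both siRNAs.

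Of the 30 lists tested, camera at the preset correlation called 3 in the same direction with both siRNAs. With an estimated correlation camera called 0 of them (0 at an unadjusted p under 0.05), fry called 8 lists, and 23 of 100 drawn splits of the 9 arrays, the real one included, gave at least 3 such lists by camera at the preset correlation. Of 12 measured histone genes, 7 rose and 1 fell with KD1 (7 and 1 adjusted over the list alone), and 6 rose and 1 fell with KD2 (8 and 2 adjusted over the list alone). Besides H2AC18, H1-2 and H2BC21, H4C8 rose by 0.98 with KD1 and 1.37 with KD2. The adjusted p from camera was 0.00454 with KD1 and 0.00491 with KD2, and the call was lost with the other setting for gene correlation: adjusted p = 0.237 with an estimated correlation for KD1 and 0.387 for KD2. With detection demanded on all arrays, the histone genes list was not called with KD1 either (adjusted p = 0.0617). Of 66 measured genes of oxidative phosphorylation, the mitochondrial pathway that makes ATP, 7 rose and 1 fell with KD1 (6 and 1 adjusted over the list alone) and 14 rose and 0 fell with KD2 (16 and 0 adjusted over the list alone). The list medians were 0.138 and 0.223. Over all 13076 features, 945 rose and 1212 fell with KD1, and 1423 rose and 1504 fell with KD2. The called share of the list was thus no higher than that of all features, while its calls were mostly rises. SDHC, a subunit gene of complex II, rose by 0.73 and 0.64, with its second probe not called with KD1 (0.35). UQCR10, of complex III, rose by 1.11 and 1.43 on the probe used, while its other probes were not called. The adjusted p was 0.0115 with KD1 and 2.69e-04 with KD2 (adjusted p = 0.247 and 0.387 with an estimated correlation), and 0.0526 with KD1 where detection was demanded on all arrays.

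Of 18 measured targets of YAP, a transcription co-activator of the Hippo pathway, 9 fell and 1 rose with KD1 (10 and 1 adjusted over the list alone), and 6 fell and 0 rose with KD2 (9 and 1 adjusted over the list alone). F3, the gene of tissue factor, changed by -1.49 with KD1 and -1.16 with KD2, and CRIM1 was 2.03-fold lower with KD1 and 1.995-fold lower with KD2. The adjusted p was 0.00231 with KD1 and 0.00531 with KD2 (adjusted p = 0.177 and 0.387 with an estimated correlation). For each of the lists called with KD1, with KD2 or between the siRNAs, the p with an estimated correlation was the highest over its 22 alternatives, while the lowest over them ranged from 9.11e-18 to 8.90e-04.

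**Figure D2:**
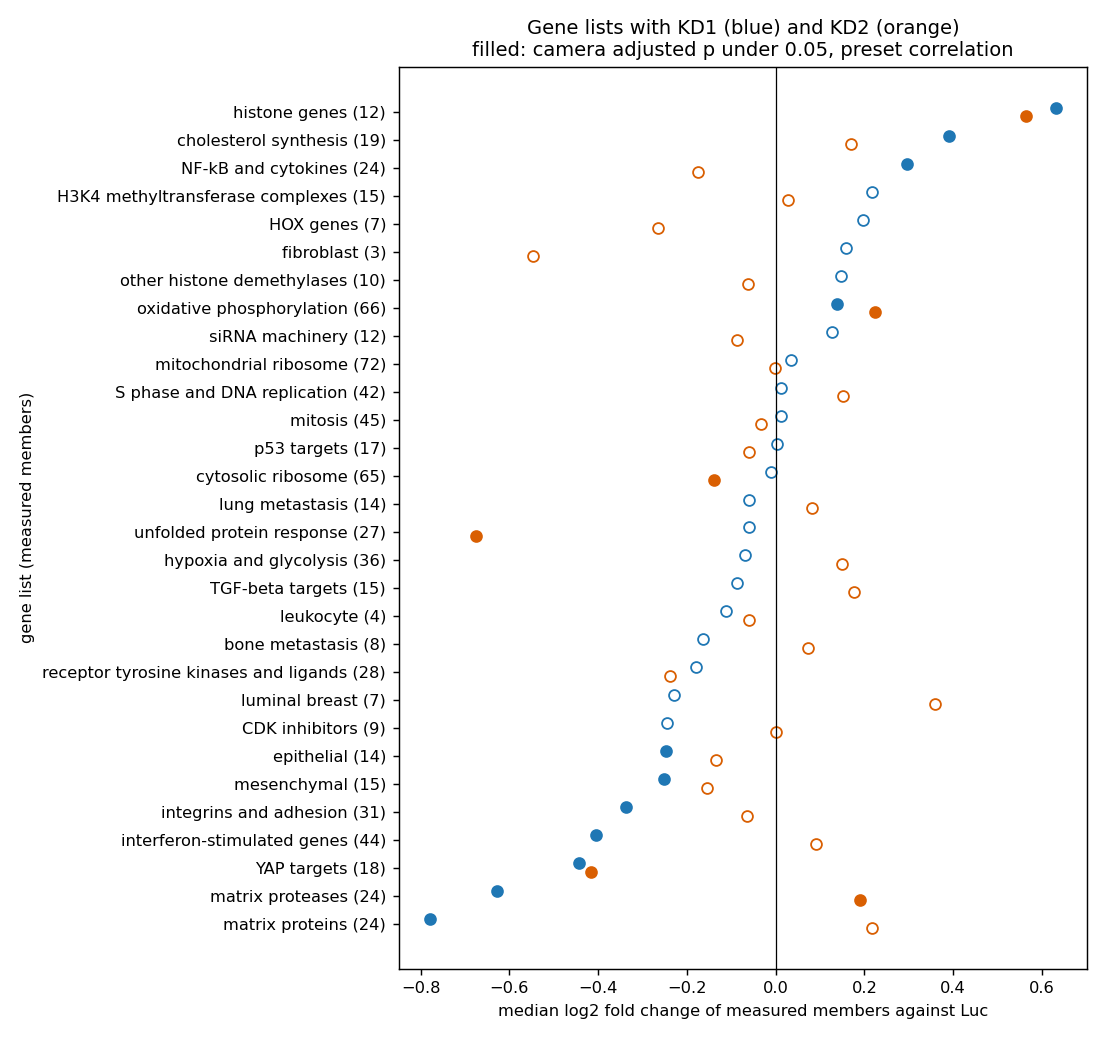
Median log2 fold change against Luc of the measured members of each of the 30 tested gene lists, with KD1 in blue and KD2 in orange; filled points are called by camera at the preset correlation, and the number of measured members stands in brackets. Histone genes lie at 0.63 with KD1 and 0.56 with KD2, whereas matrix proteins lie at -0.78 with KD1 and 0.22 with KD2.

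In KD1, SPINK4, a secreted protease inhibitor gene, fell from a mean log2 intensity of 9.16 ± 0.40 in Luc (SD, n = 3) to below detection on every KD1 array. It was at least 15.3-fold lower on the background-corrected scale, and on the deposited normalized values SPINK4, KD1 against Luc, differed by -1.80 in log2. MATN2, the gene of the matrix protein matrilin-2, changed by -3.34 on the log2 scale, IGFBP3, a binding protein of insulin-like growth factors, by -2.76, ELOVL5, a fatty acid elongase gene, by -2.63 and TNFRSF10A, a death receptor gene, by -2.06. TM4SF19 rose by 2.54, the phosphatase gene PTPRR by 2.47 (with a second, dimmer probe not called at 0.28) and FTH1P3, a ferritin heavy chain pseudogene whose probe could also read near-identical ferritin transcripts, by 2.33. TNFRSF10B, the gene of a second death receptor, rose by 1.25, with 1 of its other probes not called. In KD1 against Luc, 2157 of 13076 features were called, 945 higher and 1212 lower, of which 487 had an absolute log2 fold change of at least 1. Leaving out Luc replicate 2 gave 1381 calls. With median scaling, KD1 against Luc gave 1243 higher and 1032 lower, 54.6% higher in place of 43.8%.

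Of 24 measured matrix protein genes, 16 fell and 0 rose with KD1 (16 and 0 adjusted over the list alone), with LAMB1, a laminin chain gene, at -1.20 and MATN2 at -3.34 (adjusted p = 1.75e-09 by camera; adjusted p = 0.104 with an estimated correlation). COL5A1, a collagen chain gene, was 4.27-fold lower. TNC, the gene of the matrix glycoprotein tenascin C, changed by -0.75, while its second probe was not called with KD1 (-0.07). Among 44 measured interferon-stimulated genes, 18 fell and 0 rose (22 and 0 adjusted over the list alone). IFIT2 changed by -1.93 and IFIT1 by -1.93, with a second, dimmer IFIT1 probe not called (-0.12), and ISG15, a ubiquitin-like modifier gene, by -1.40. The adjusted p of this list was 5.93e-09, and it was the 1 list called with KD1 at an estimated correlation (adjusted p = 0.00883 with an estimated correlation). Of 24 measured genes of matrix proteases and their regulators, 12 fell and 1 rose (13 and 2 adjusted over the list alone; adjusted p = 1.68e-04, and adjusted p = 0.104 with an estimated correlation). The list holds protease inhibitors as well: SERPINE2, which encodes one, changed by -1.38, ADAM9 by -0.97 and ADAM17 by -0.84 (its 2 other probes were not called), and PLAUR, the urokinase receptor gene, by 0.75.

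Of 31 measured genes of integrins and adhesion, 8 fell and 1 rose with KD1 (12 and 3 adjusted over the list alone), with CAV2, a caveolin gene, at -1.85 and PXN, which encodes the focal adhesion protein paxillin, at 0.81 (adjusted p = 6.99e-04; adjusted p = 0.104 with an estimated correlation). Epithelial and mesenchymal lists both moved down. Of 14 measured epithelial genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone), with CLDN1, of tight junctions, at -0.68 and PKP2, of desmosomes, at -0.84 (adjusted p = 0.0115; adjusted p = 0.104 with an estimated correlation). Of 15 measured mesenchymal genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone), with LOX, a collagen cross-linking enzyme gene, at -1.39 and TGFBR2 at -1.16, the latter with a dim probe not called (adjusted p = 0.0275; adjusted p = 0.125 with an estimated correlation). Of 19 measured genes of cholesterol synthesis, 7 rose and 1 fell (9 and 1 adjusted over the list alone), with HMGCS1 at 1.09 and IDI1 at 0.97, both enzymes of the mevalonate pathway (adjusted p = 0.00396; adjusted p = 0.104 with an estimated correlation). Of 24 measured genes of NF-kB and cytokines, 7 rose and 2 fell (11 and 2 adjusted over the list alone), with the cytokine gene IL1A at 0.89 and the chemokine gene CCL5 at -1.29. That list's call (adjusted p = 0.0268) was lost with median scaling (adjusted p = 0.0630) and at the other gene correlation (adjusted p = 0.117 with an estimated correlation).

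With KD2 against Luc, CST1, which encodes a secreted cystatin, rose by 4.25 on the log2 scale from 8.66 ± 0.24 in Luc to 12.9 ± 0.02 in KD2 (SD, n = 3 each), and its relative CST4 by 2.91. CST1 and CST4 are near-identical family members, so their probes could read each other's transcripts. CCNA1, the gene of cyclin A1, rose by 2.61 and MLLT11 by 2.33. GDF15, a stress-induced cytokine gene, fell by 3.10 from 10.7 ± 0.17, DDIT3, the gene of the stress transcription factor CHOP, changed by -2.96, TRIB3, a pseudokinase gene, by -2.66, PDE9A by -2.97 (with a second, dimmer probe not called at -0.64), and ASS1, a gene of arginine synthesis, by -2.82 (second probe -1.22). CXCR4, a chemokine receptor gene, was detected only on KD2 arrays and was at least 2.51-fold higher than in Luc on the background-corrected scale, with a second probe not called (0.73). On the deposited normalized values CXCR4, KD2 against Luc, differed by 0.40 in log2. In KD2 against Luc, 2927 features were called, 1423 higher and 1504 lower, of which 609 had an absolute log2 fold change of at least 1.

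Of 27 measured genes of the unfolded protein response, the program that follows misfolded proteins in the endoplasmic reticulum, listed with targets of ATF4, 14 fell and 3 rose with KD2 (14 and 4 adjusted over the list alone). Besides DDIT3 and TRIB3, PSAT1, of serine synthesis, changed by -1.24 and the transcription factor gene XBP1 by -0.69. The adjusted p was 2.69e-04 (adjusted p = 0.140 with an estimated correlation). Of 65 measured genes of the cytosolic ribosome, 13 fell and 0 rose (13 and 0 adjusted over the list alone), with RPL13A at -0.78 and RPL37 at -1.19 (second probe not called, 0.05). The probes of RPL34 opposed each other, at -0.61 on the probe used and 1.64 on the other, both called. The list's adjusted p was 0.00369 (adjusted p = 0.394 with an estimated correlation) and its call was lost with median scaling (adjusted p = 0.103), where its median was -0.05 with KD2 and 0.17 with KD1, the latter called higher (adjusted p = 0.0364, with a range of 0.0364 to 0.992 over that list's alternatives with KD1). Of 24 measured genes of matrix proteases and their regulators, 8 rose and 3 fell with KD2 (10 and 4 adjusted over the list alone), with MMP9, a gelatinase gene, at 2.33, PLAUR at 1.36 and SERPINE2 at -0.99. This list's adjusted p was 0.00912 (adjusted p = 0.387 with an estimated correlation), and 0.214 where detection was demanded on all arrays. None of the 30 lists was called with KD2 at an estimated correlation. From camera 2 had an unadjusted p under 0.05 there, and fry, which tests whether the genes of a list move 1 way on balance, called 20.

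The siRNAs were then compared directly. In KD1 against KD2, 3579 features were called, 1737 higher and 1842 lower with KD1, of which 905 differed by at least 1 on the log2 scale. CST1 differed by -6.14, from a mean of 6.76 in KD1 to 12.9 in KD2, and CST4 by -3.61. MMP9 was not detected on any KD1 array. On the background-corrected scale MMP9 was at least 10.7-fold lower and SPINK4 at least 9.84-fold lower with KD1 than with KD2. On the deposited normalized values MMP9, KD1 against KD2, differed by -1.40 and SPINK4, KD1 against KD2, by -1.35 in log2, both called. EFEMP1, the gene of a matrix protein of the fibulin family, differed by -3.20 on the scale used here. GDF15 was higher with KD1 than with KD2 by 3.30, BEX2 by 3.07, DDIT3 by 2.84, PTPRR by 2.70 and the chemokine gene CXCL2 by 2.69. Of the 3342 features called with 1 siRNA alone, 2272 also differed between the siRNAs by this test, and so did all 163 called in opposite directions and 153 called in the same direction.

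Of 24 measured genes of matrix proteases and their regulators, 15 were lower and 0 higher with KD1 than with KD2 (16 and 0 adjusted over the list alone), PLAUR by -0.61 (adjusted p = 2.63e-09; adjusted p = 0.0376 with an estimated correlation). Of 44 measured interferon-stimulated genes, 25 were lower and 1 higher with KD1 (26 and 2 adjusted over the list alone), with IFIT2 at -1.64, ISG15 at -1.59 and IFIT1 at -1.16 (adjusted p = 2.72e-09; adjusted p = 0.00795 with an estimated correlation). Of 24 matrix protein genes, 15 were lower and 4 higher with KD1 (16 and 4 adjusted over the list alone), with MATN2 at -2.55, COL5A1 at -1.15 and TNC at 1.08 (adjusted p = 1.97e-05; adjusted p = 0.185 with an estimated correlation). Of 36 measured genes of hypoxia and glycolysis, 11 were lower and 2 higher (11 and 2 adjusted over the list alone), with ADM, the adrenomedullin gene, at -0.82 (adjusted p = 0.0120; adjusted p = 0.233 with an estimated correlation). Higher with KD1 than with KD2 were 13 of 27 genes of the unfolded protein response, with 5 lower (15 and 5 adjusted over the list alone; adjusted p = 0.00665, and adjusted p = 0.130 with an estimated correlation), a call lost where detection was demanded on all arrays (adjusted p = 0.0551). Of 65 cytosolic ribosome genes, 12 were higher and 0 lower (10 and 0 adjusted over the list alone), with RPL37 at 1.67 and RPL13A at 1.04 (adjusted p = 0.00665; adjusted p = 0.322 with an estimated correlation). Of 24 genes of NF-kB and cytokines, 12 were higher and 1 lower (12 and 1 adjusted over the list alone; adjusted p = 0.0120, and adjusted p = 0.130 with an estimated correlation).

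**Figure D3:**
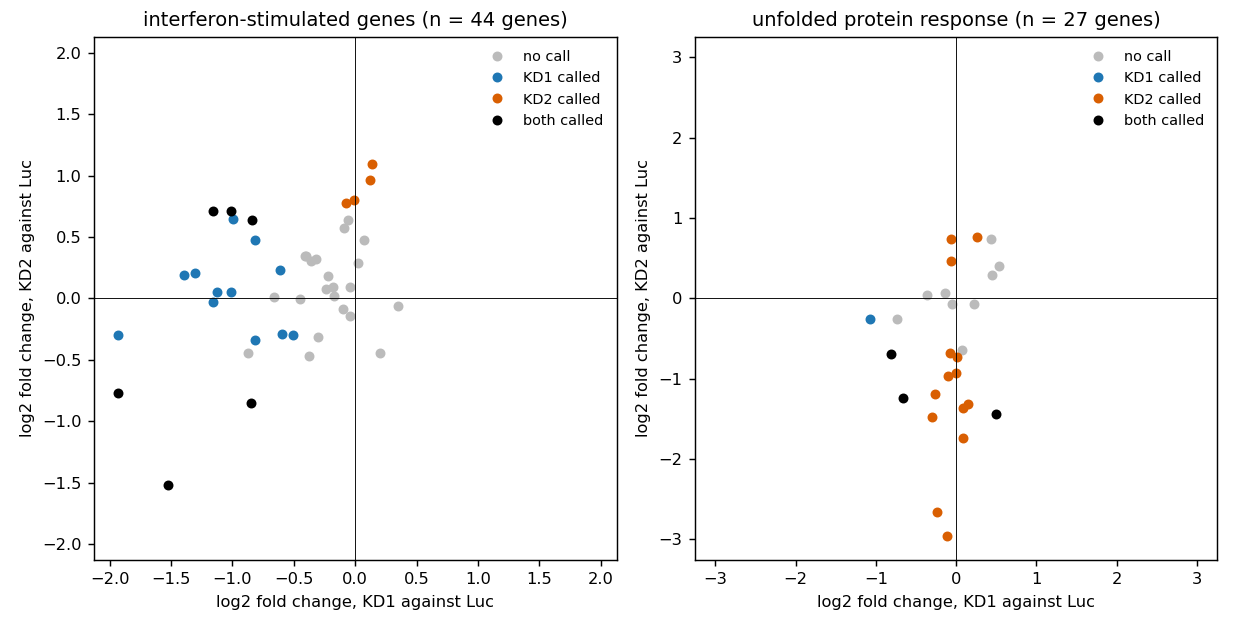
Log2 fold change against Luc with KD1 (horizontal) and KD2 (vertical) of the 44 measured interferon-stimulated genes and the 27 measured genes of the unfolded protein response; colour marks which siRNA gave a call. Of the interferon-stimulated genes 18 fell and 0 rose with KD1, and 3 fell and 7 rose with KD2. Of the unfolded protein response genes 3 fell and 1 rose with KD1, and 14 fell and 3 rose with KD2.

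Camera at the preset correlation called no cell-cycle list with either siRNA, although single members moved. With KD2, fry, which does not compare a list with other genes, called S phase and DNA replication higher (adjusted p = 0.0266, with a range up to 0.610 over the alternatives), CDK inhibitors higher (0.0317, up to 0.872) and p53 targets lower (0.00225, up to 0.597). Camera with no detection filter also called S phase and DNA replication with KD2 (adjusted p = 0.0470). Of 42 measured genes of S phase and DNA replication, 2 rose and 3 fell with KD1 (2 and 2 adjusted over the list alone; adjusted p = 0.703). With KD2, 9 rose and 5 fell (10 and 5 adjusted over the list alone; adjusted p = 0.256). RPA1, the gene of a single-strand DNA binding protein, rose by 1.19 and 1.35 and MCM4, a replicative helicase gene, by 0.57 and 0.65, the latter with a second probe not called. Of 45 mitosis genes, 5 rose and 7 fell with KD1 (5 and 8 adjusted over the list alone; adjusted p = 0.958). With KD2, 6 rose and 6 fell (8 and 6 adjusted over the list alone; adjusted p = 0.957), with KIF20A, a mitotic kinesin gene, at 0.77 and 1.04. Of 9 CDK inhibitor genes, 1 rose and 2 fell with KD1 (2 and 3 adjusted over the list alone; adjusted p = 0.958). With KD2, 1 rose and 0 fell (2 and 2 adjusted over the list alone; adjusted p = 0.698). CDKN1A, the gene of p21, rose by 0.70 with KD1 and 1.22 with KD2. CDKN1B, the gene of p27, changed by -0.42 with KD1 (adjusted p = 0.0368) and was not called with KD2 (0.00), and its second probe was not called with either. The CDKN1B call was lost without Luc replicate 1 (adjusted p = 0.0888), Luc replicate 2 (0.0708), Luc replicate 3 (0.0943), KD2 replicate 1 (0.0504), KD2 replicate 2 (0.0544), KD2 replicate 3 (0.0501), KD1 replicate 1 (0.0897) or KD1 replicate 3 (0.118), and its leave-one-out adjusted p started at 0.0379. Of 17 p53 targets, 4 rose and 3 fell with KD1 (5 and 4 adjusted over the list alone; adjusted p = 0.958). With KD2, 3 rose and 7 fell (3 and 7 adjusted over the list alone; adjusted p = 0.397).

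Camera at the preset correlation called neither metastasis list nor the other lists of this set. By fry, lung metastasis was lower with KD1 (adjusted p = 0.0171, with a range up to 0.853 over the alternatives), and bone metastasis was lower with KD1 (0.0128, up to 0.586) and higher with KD2 (0.0264, up to 0.945). Fry also called TGF-beta targets higher with KD2 (adjusted p = 5.61e-05, up to 0.394), and receptor tyrosine kinases and ligands lower with KD1 (3.36e-05, up to 0.307) and KD2 (0.0404, up to 0.968). Camera called TGF-beta targets with KD2 when no detection filter was used (adjusted p = 0.0470) or every probe was a feature (0.0380), and receptor tyrosine kinases and ligands with KD1 with no detection filter (0.0197) or with median scaling (0.0494). Of 14 measured genes of the lung metastasis list, 2 rose and 4 fell with KD1 (4 and 5 adjusted over the list alone; adjusted p = 0.703). With KD2, 3 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.691). TNC, on that list, changed by -1.82 with KD2, with its second probe at -0.95, and MMP1, a collagenase gene, was at 0.03 and 0.08 (adjusted p = 0.954 and 0.846). Of 8 bone metastasis genes, 1 rose and 2 fell with KD1 (1 and 2 adjusted over the list alone; adjusted p = 0.355). With KD2, 2 rose and 1 fell (2 and 1 adjusted over the list alone; adjusted p = 0.691), with FST, the follistatin gene, at 1.08 with KD2. VIM, the vimentin gene, was at -0.25 and 0.11 and was not called, and CDH1 was not detected on enough arrays to be tested. Of 15 TGF-beta targets, 2 rose and 4 fell with KD1 (3 and 4 adjusted over the list alone; adjusted p = 0.944). With KD2, 5 rose and 2 fell (5 and 3 adjusted over the list alone; adjusted p = 0.206), with SMAD7, an inhibitor of the pathway, at 0.995 and 1.13 and a second probe not called with KD1. Of 28 receptor tyrosine kinases and ligands, 1 rose and 5 fell with KD1 (1 and 5 adjusted over the list alone; adjusted p = 0.0737). With KD2, 7 rose and 5 fell (8 and 6 adjusted over the list alone; adjusted p = 0.922), with HBEGF, a ligand of the EGF receptor, at 0.76 and 1.15.

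Other histone demethylases, H3K4 methyltransferase complexes, HOX genes, siRNA machinery and mitochondrial ribosome lists were not called by camera at the preset correlation, and of these fry called HOX genes lower with KD2 (adjusted p = 0.00141, with a range up to 0.949 over the alternatives). Of 10 measured other histone demethylases, 0 rose and 1 fell with KD1 (0 and 1 adjusted over the list alone; adjusted p = 0.958). With KD2, 1 rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.922). Of 15 genes of H3K4 methyltransferase complexes, 1 rose and 2 fell with KD1 (1 and 2 adjusted over the list alone; adjusted p = 0.598). With KD2, 0 rose and 3 fell (0 and 3 adjusted over the list alone; adjusted p = 0.691). Of 7 HOX genes, 1 rose and 1 fell with KD1 (1 and 1 adjusted over the list alone; adjusted p = 0.958). With KD2, 0 rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.397), with HOXD1 at -1.08 and -0.79. Of 12 genes of the siRNA machinery, 2 rose and 2 fell with KD1 (4 and 2 adjusted over the list alone; adjusted p = 0.452). With KD2, 0 rose and 2 fell (1 and 4 adjusted over the list alone; adjusted p = 0.691), with AGO1, an Argonaute gene, at 0.88 with KD1. Of 72 mitochondrial ribosome genes, 2 rose and 3 fell with KD1 (1 and 0 adjusted over the list alone; adjusted p = 0.690). With KD2, 5 rose and 4 fell (3 and 3 adjusted over the list alone; adjusted p = 0.969), with MRPL52 at 0.65 and 0.98.

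Markers of other cell types were not called by camera at the preset correlation, and fry called luminal breast genes lower with KD1 (adjusted p = 8.90e-04, with a range up to 0.549 over the alternatives) and higher with KD2 (0.00490, up to 0.691). Of 7 measured luminal breast genes, 0 rose and 1 fell with KD1 (0 and 1 adjusted over the list alone; adjusted p = 0.452). With KD2, 1 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.397). Of 4 leukocyte genes, 2 rose and 2 fell with KD1 (2 and 2 adjusted over the list alone; adjusted p = 0.958). With KD2, 1 rose and 0 fell (1 and 0 adjusted over the list alone; adjusted p = 0.925): CD68, a lysosomal gene, rose by 0.93 and 0.62, and with KD1 LCP1 was at 1.03, LAPTM5 at -1.19 and CD14 at -1.15. Of 3 fibroblast genes, 0 rose and 0 fell with KD1 (0 and 0 adjusted over the list alone; adjusted p = 0.958). With KD2, 1 rose and 0 fell (1 and 2 adjusted over the list alone; adjusted p = 0.957). The remaining lists not called against Luc by camera at the preset correlation were, with KD1, the cytosolic ribosome (2 rose and 1 fell of 65, 1 and 1 adjusted over the list alone; adjusted p = 0.958), the unfolded protein response (1 rose and 3 fell of 27, 1 and 3 adjusted over the list alone; adjusted p = 0.554) and hypoxia and glycolysis (3 rose and 5 fell of 36, 3 and 6 adjusted over the list alone; adjusted p = 0.355). With KD2 these were matrix proteins (5 rose and 8 fell of 24, 10 and 9 adjusted over the list alone; adjusted p = 0.957), integrins and adhesion (4 and 5 of 31, 4 and 5 adjusted over the list alone; 0.957), mesenchymal genes (1 and 3 of 15, 1 and 4 adjusted over the list alone; 0.709) and epithelial genes (2 and 6 of 14, 3 and 6 adjusted over the list alone; 0.358). They also were interferon-stimulated genes (7 and 3 of 44, 8 and 3 adjusted over the list alone; adjusted p = 0.358), NF-kB and cytokines (3 and 9 of 24, 6 and 10 adjusted over the list alone; 0.358), hypoxia and glycolysis (8 and 2 of 36, 8 and 2 adjusted over the list alone; 0.187) and cholesterol synthesis (4 and 1 of 19, 4 and 1 adjusted over the list alone; 0.187). Of these, fry called the unfolded protein response lower with KD1 (adjusted p = 0.0229, with a range up to 0.812 over the alternatives). With KD2 it called mesenchymal genes (adjusted p = 0.0172, up to 0.979), epithelial genes (0.00195, up to 0.457) and NF-kB and cytokines (0.00195, up to 0.472) lower. It called interferon-stimulated genes (adjusted p = 0.00506, up to 0.488), hypoxia and glycolysis (0.00527, up to 0.422) and cholesterol synthesis (0.00195, up to 0.387) higher. With no detection filter camera called hypoxia and glycolysis (adjusted p = 0.0305) and cholesterol synthesis (0.0278) with KD2, and with every probe a feature hypoxia and glycolysis (0.0498).

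The median, the mean and the camera test of a list differed in sign only among lists that camera did not call at the preset correlation. With KD1 these were other histone demethylases (median 0.15, mean -0.05, test up), leukocyte (-0.11, -0.10, up), fibroblast (0.16, -0.04, down), mitosis (0.01, -0.02, up), p53 targets (0.00, -0.04, up) and the cytosolic ribosome (-0.01, 2.61e-03, up). With KD2 they were H3K4 methyltransferase complexes (0.03, -0.10, down), matrix proteins (0.22, -0.08, up), leukocyte (-0.06, 0.04, up), fibroblast (-0.55, 0.05, down) and the mitochondrial ribosome (-1.21e-03, -0.01, up). Between the siRNAs they were other histone demethylases (0.12, -0.01, up), epithelial genes (0.02, -0.05, down), fibroblast (0.79, -0.09, up), mitosis (-0.01, -5.25e-04, up) and p53 targets (-0.08, 0.19, up). In the mean contrast they were 9 lists, among them matrix proteases (-0.04, 0.03, up) and TGF-beta targets (-0.02, 0.16, up).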

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

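The 3 histone tests and the test of a rise with the control siRNA were chosen after the results they measure were seen. The tests of array position and of dim probes were set before.

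KD1 and KD2 are aimed at the same gene, and their effects against Luc differed by the direct test for many features. All 163 features called in opposite directions differed in KD1 against KD2, as did 2272 features called with 1 siRNA alone. KD1 minus KD2 was -6.14 for CST1, -3.20 for EFEMP1, -2.92 for ITGA10, -2.71 for CAV2 and 2.69 for CXCL2 on the log2 scale. MMP9 was below detection with KD1. The size of its difference depends on the treatment of the background: for MMP9, KD1 against KD2, the fitted value was -3.69, which is no bound (-2.74 with an offset of 50 and -1.40 on the deposited normalized values). Of these genes, ITGA10 lost its KD1 call against Luc without Luc replicate 1 (adjusted p = 0.0822), Luc replicate 2 (0.113), KD1 replicate 1 (0.0733) or KD1 replicate 2 (0.0954), with a leave-one-out range of 0.0260 to 0.113. CXCL2 lost its KD1 call against Luc without Luc replicate 1 (adjusted p = 0.130), Luc replicate 2 (0.0662), Luc replicate 3 (0.0698), KD2 replicate 1 (0.0552), KD1 replicate 1 (0.113) or KD1 replicate 2 (0.1002), with a leave-one-out range of 0.0208 to 0.130. By camera the siRNAs differed for matrix proteases (adjusted p = 2.63e-09), interferon-stimulated genes (2.72e-09), matrix proteins (1.97e-05), the cytosolic ribosome (0.00665), the unfolded protein response (0.00665), NF-kB and cytokines (0.0120) and hypoxia and glycolysis (0.0120). With an estimated correlation only the first 2 of these lists kept their call (adjusted p = 0.0376 and 0.00795), and the others had 0.185, 0.322, 0.130, 0.130 and 0.233 in the same order. The siRNA sequences are not used here and the level of KDM5A is not analysed here. Off-target effects were therefore not tested for these differences. A stronger knockdown by 1 siRNA was not tested for features called with 1 siRNA alone or in the same direction. For the 163 called in opposite directions, the signs argue against it as the only cause, if more knockdown moves a transcript further the same way. Against Luc, CST1 was at -1.897 with KD1 and 4.247 with KD2, and EFEMP1 at -2.065 and 1.133. The KD1 arrays lay at slide positions G, I and K and the others at A to F. An effect of those positions cannot be told apart from an effect of KD1.

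Some replication-dependent histone transcripts were higher with both siRNAs: of 20 measured genes, 10 were called higher with each siRNA, 8 with both, and 1 was lower with both. The histone genes list lost its call with an estimated correlation (adjusted p = 0.237 with KD1 and 0.387 with KD2). The per-array mean of these 20 genes differed from Luc by 0.736 (95% interval 0.546 to 0.925) with KD1 and by 0.602 (0.412 to 0.791) with KD2. An off-target effect of one siRNA is not decided for the genes of this class: 8 of the 12 called higher with either siRNA were called higher with both, but that count restates the pattern, and both calls use the same 3 Luc arrays. An effect that both siRNAs share without KDM5A was not tested. One transcript read by several histone probes is argued against as the whole pattern, since the 8 genes are of 5 histone types. H4C3 was lower with both siRNAs (-0.76 and -0.88), so the class did not move as a whole. More cells in S phase cannot be told apart from other explanations: the mean of the S phase and DNA replication list differed from Luc by 0.0258 with KD1 (-0.0815 to 0.133), whose upper end passes the limit of 0.1 set for the test, and by 0.109 with KD2 (0.00176 to 0.216). A change in the processing of histone transcripts was not tested. The reduction of KDM5A, which the design names, stays open as untested.

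Interferon-stimulated genes as a list were lower with KD1, with a per-array mean of -0.548 against Luc (-0.589 to -0.506) and -0.660 against KD2. KD1 arrays lie apart from the others on the slide. A linear trend with array position within Luc and KD2 predicts a shift of -0.0104 (-0.0739 to 0.0531), which argues against such a trend as the cause, while an effect confined to the KD1 positions stays open. A shift of dim probes is argued against: the 25 members with a mean log2 intensity over 8 had a median of -0.32 (quartiles -0.818 and -0.0774), with 10 called lower and 0 called higher in limma. For the list mean a rise with the control siRNA alone is argued against, since KD2 lay above Luc by 0.112 (0.0707 to 0.154). It stays open for the 3 members called lower with both siRNAs: IFIT1 (-1.93 with KD1, -0.77 with KD2), IFI44L (-0.85, -0.86) and XAF1 (-1.53, -1.52). No arrays of untransfected cells are among the samples, so a fall with KD1 cannot be told apart from a rise that Luc and KD2 share. Culture or handling that the KD1 arrays share, an off-target effect of KD1 and the reduction of KDM5A stay open as untested.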

How the results depend on the processing

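The target's level, with every alternative set for it, was not run because no probe carried the symbol KDM5A. Requiring an absolute log2 fold change of at least 1 lowered the counts by construction, to 487 for KD1 against Luc, 609 for KD2 against Luc, 89 for both siRNAs against Luc, 241 for both siRNAs against Luc, mean contrast, and 905 for KD1 against KD2. The count for both siRNAs against Luc was 1107 with no background correction, 1113 on the deposited normalized values, where the cause was not tested, and 461 with no detection filter, where 39555 features were tested. Leaving out each array in turn gave 1381 to 2058 calls for KD1 against Luc, 2025 to 2962 for KD2 against Luc, 410 to 608 for both siRNAs against Luc, 1204 to 2144 for both siRNAs against Luc, mean contrast, and 2781 to 3448 for KD1 against KD2. The lowest count for the first 4 came without Luc replicate 2, and fewer control arrays widen the error of each comparison against Luc.

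The gene lists called with both siRNAs (3) were 1 with a detection p under 0.01 on all arrays, 0 by camera with an estimated correlation (0 with an unadjusted p under 0.05) and 8 by fry. By camera with an estimated correlation the gene lists called in KD1 against Luc went from 11 to 1 (9 with an unadjusted p under 0.05). In KD2 against Luc they went from 6 to 0 (2 with an unadjusted p under 0.05) and in KD1 against KD2 from 7 to 2 (5 with an unadjusted p under 0.05). By fry, which does not compare a list with other genes, 20 were called in KD2 against Luc and 21 in KD1 against KD2. With no detection filter they were 10 and 13, and the cause was not tested. Leaving out each array gave 7 to 8 lists in KD1 against KD2 and no change in the other list counts.

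Same-numbered arrays share a number only: their residuals correlated from -0.0237 to 0.107, over 0.1 in 1 of 9 pairs, and 4 of 9 arrays correlated best with an array of their own number. The replicate block gave 1977 calls in KD1 against Luc, 2793 in KD2 against Luc, 644 for both siRNAs against Luc, 2068 for both siRNAs against Luc, mean contrast, and 3376 in KD1 against KD2. The lists called were 11, 6 and 7, and 3 with both siRNAs.

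No value of a named gene or list that was called in the main fit changed sign under any alternative run. The cytosolic ribosome list with KD1, not called in the main fit (median -0.01), was called higher by camera with median scaling (median 0.17). Of 288 values of named genes, 270 kept their side of the threshold on the deposited normalized values, with 10 calls gained and 8 lost. With median scaling 277 kept it, with no detection filter 261, and with the replicate block 272. Over the leave-one-out fits 2389 of 2592 kept it, with 196 calls lost and 7 gained, and 41 of 238 calls of named genes were lost in at least 1 fit. Of 90 list results 86 kept their side with median scaling, and 809 of 810 did over the leave-one-out fits. The mean contrast has no value with only the 2 groups compared. Signal over background limits dim probes: 226 of the named values could be tested with detection on all arrays.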

Other observations

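The test of ATF4 targets was chosen after the result it measures was seen, and the NRF2, ATF4 and ER chaperone lists were written after the data were seen. The counts over other splits of the arrays and the NRF2 prediction were set before their results.

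HMOX1 and GCLM, the latter chosen after its values were seen, were higher with both siRNAs (GCLM 1.37 with KD1 and 1.21 with KD2). Activity of NRF2, a transcription factor of the oxidative stress response, may link them. NRF2 targets without these genes were called higher by camera with KD1, with 8 of 20 genes higher and 0 lower (median 0.325, adjusted p = 3.34e-05, and 0.0150 with an estimated correlation). With KD2, 4 were higher and 1 was lower, NQO1 at -0.47 (list median 0.143, adjusted p = 0.114, and 0.197 with an estimated correlation). A shared rise is therefore left undecided, since the smaller median of 0.143 is above the limit of 0.1 set for its absence and the KD2 test was not past its threshold.

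The unfolded protein response list was called lower with KD2 at the preset correlation (adjusted p = 2.69e-04) and not with an estimated one (adjusted p = 0.140). A candidate explanation is lower activity of ATF4, a transcription factor of the amino acid response, without a fall of ER chaperones. Of 23 measured ATF4 targets, 21 were lower and 0 higher with KD2 (median -0.938, adjusted p = 1.29e-16 by camera, and 7.04e-04 with an estimated correlation). Of these targets 8 are also on the unfolded protein response list, and of the 15 that are not, 13 were lower with KD2 (median -0.84). Of 15 ER chaperones, 13 of them on that list, 3 were higher and 0 lower (adjusted p = 0.234), and their per-array mean lay above Luc by 0.127 (95% interval 0.0152 to 0.240). The shift of ATF4 targets minus that of ER chaperones was -1.14 with KD2 (95% interval -1.25 to -1.03), which is in line with this hypothesis, found and tested on the same arrays. With KD1, 2 ATF4 targets were higher and 3 lower (adjusted p = 0.438), and KD1 against KD2 gave 20 higher and 0 lower (adjusted p = 1.22e-12). Growth conditions such as medium or cell density, which can act on ATF4, are not given in the labels and were not tested.

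Comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. Only 1 split, the real one, gave as many calls in KD1 against Luc (2157, highest other 0), in KD2 against Luc (2927, highest other 0) and in KD1 against KD2 (3579, highest other 0). For lists, only 1 split, again the real one, gave as many in KD1 against Luc (11, highest other 4), KD2 against Luc (6, highest other 3) and KD1 against KD2 (7, highest other 5). Over 100 drawn splits of the 9 arrays into 3 groups, 3 gave as many features called with both siRNAs as the real 708, the real one included. The highest other was 979, and both splits above the real one set the 3 KD2 arrays as the control group, which points to a structure of the samples. Every split with such calls kept a real group whole as its control group. The share under 0.05 thus argues against a random grouping of the arrays. It does not show an overlap particular to Luc as the control. For the mean contrast 1 split gave as many as the real 2259 (highest other 2047), and this too argues only against a random grouping. For lists called with both siRNAs, 23 of 100 splits gave at least the real 3 (highest other 6), so chance is not excluded.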
